A study of Solanum lycopersicum with 4 samples.

How the data were processed

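Poly(A)-selected RNA from tomato fruit (Solanum lycopersicum, cultivar Ailsa Craig) was sequenced in 4 libraries, 2 from fruit of plants that carry the citrus gene CsMYBF1 and 2 from wild-type fruit. Per the labels' protocols, RNA was extracted with Trizol, mRNA was enriched on oligo(dT) beads and fragmented, and cDNA was primed with random hexamers and ligated to adaptors. That protocol names no step that marks the strand, and whether counting used the strand is not stated, so reads of overlapping antisense genes may not have been kept apart. The values are RPKM (reads per kilobase of gene length per 1000000 reads of the library), computed by the authors and deposited as 1 table with a column per library and a Solyc gene ID per row. HTSeq is named in the submitters' processing notes, without a version. The aligner, the genome build, the annotation release, the treatment of reads that map to several places and any filter are not given in the sources used here. The 4 columns were matched to samples by the line name or replicate number in their headers. Groups were taken from the sample descriptions. The transgenic libraries are replicate 1 from line D7 and replicate 2 from line C2. Nothing in the labels says whether the wild-type samples came from separate plants, so p-values measure only the spread between these samples, which is partly a spread between lines in the transgenic group and may be technical in the wild type.

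Gene names were not available for this comparison. Of the Solyc IDs, 0 were found in the reference gene table, which lists 41476 genes, and the deposited table marks 1 gene with a name, Slchs. The 18 gene lists and 10 enzyme families fixed as patterns on gene descriptions before the data were examined were therefore not tested. By the naming rule fixed at the same time, the genes with the largest rise and the largest fall among genes past the threshold whose groups do not overlap were to be named, with at most 2 unnamed IDs printed per direction. Slchs was added because the table names it. The chromosome of a gene was read from the digits after "Solyc" in its ID, where 00 stands for unplaced sequence. No coordinates are given.

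The deposited table gives no read counts, but low RPKM values stepped in whole multiples of the value of a single read. The library totals and the smallest whole-number length of each gene at which its 4 values gave whole reads were solved from these steps, for lengths from 60 to 20000 bases and with a tolerance of 0.001 reads. Of the 24422 genes above 0 in any library, 24420 (99.99%) were solved. With library totals that were deliberately wrong, 10.8% of 3000 genes were solved. Recovered lengths were multiples of 3 for 93.3% of gene models whose ID ends in version 1 and for 33% of models whose ID ends in version 2, so most lengths of version 1 models are coding lengths. On simulated RPKM of 5892 genes the procedure returned all 4 library totals exactly and the right 4 read numbers for 95.94% of genes. Recovered lengths are lower limits where a gene's reads and length share a factor. The recovered totals were 15227619 reads for transgenic replicate 1, 12916160 for transgenic replicate 2, 21403774 for wild-type replicate 1 and 13101910 for wild-type replicate 2. At these depths 3 reads in a gene of 1 kilobase correspond to 0.197, 0.232, 0.14 and 0.229 RPKM in the same order. Floors and intervals based on reads cover counting error only, and reads without molecular identifiers are not independent molecules.

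The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(RPKM + 1), for genes with a mean RPKM of at least 1 over the 4 libraries, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. Every adjusted p comes from this limma fit unless another setting is named. In simulated data with 200 changed genes among 16525, averaged over 10 runs, the fit called 0% of 2-fold rises, 1.4% of 4-fold rises, 43.8% of 8-fold rises and 1.6% of 4-fold falls, and 1.5 unchanged genes per run. The simulated data hold far fewer changed genes than the real comparison called, and the Benjamini-Hochberg threshold is stricter where few genes change. Their spread was taken from the real libraries, which already holds counting error, and counting error was then added again. The shares called may therefore be too low. Medians of gene classes are given with 95% bootstrap intervals over genes, which are not independent replicates.

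Alternatives fixed before the data were examined were other pseudocounts and filters, median-of-ratios scaling, quantile normalization, other eBayes settings, the replicate number as a block and leaving out each library. Added after seeing the data were voom (limma) on the recovered reads, a correction for gene length by loess with a span of 0.3, a fit without genes at 0 in both libraries of a group, a scaling to the summed RPKM without the 10 most abundant genes, library totals without the reads of these genes and a crossed block. The models of raw reads that had been planned for a table of counts were not run, because the deposited unit is RPKM. The number of columns of per-sample values left unused was 0. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.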

Results

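Gene expression was measured by RNA sequencing in fruit of tomato plants that carry CsMYBF1, a citrus gene for a MYB transcription factor, and in wild-type fruit. MYB factors of this class are regulators of phenylpropanoid and flavonoid genes. The transgenic group held 2 libraries, replicate 1 from line D7 and replicate 2 from line C2, and the wild-type group held 2 libraries. The table listed 34675 genes, of which 10253 were at 0 in all 4 libraries. At least 1 RPKM was reached by 17165 genes in line D7, 16714 in line C2, 15814 in wild-type replicate 1 and 15568 in wild-type replicate 2. The recovered depth was 12916160 to 21403774 reads per library, with the deepest library in the wild-type group.

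The comparison addressed which genes differ between fruit of the CsMYBF1 lines and wild-type fruit. Rows of the table carry tomato gene IDs, so the level of the citrus gene itself was not measured here. Differences between the groups are therefore not shown to be effects of CsMYBF1. Of 16876 genes tested, 3179 were higher and 352 were lower in the transgenic libraries (limma on log2(RPKM + 1), adjusted p below 0.05). Genes called higher had a median log2 fold change of 1.64, and genes called lower a median of -1.37. A change of at least 4-fold was found for 570 of the genes called higher and 49 of the genes called lower. The log2 fold change had a median of 0.49 over all genes tested, and 90% of the called genes were higher. With median-of-ratios scaling, which moved that median to -0.05, 498 genes were higher and 926 lower, and 35% of the called genes were higher. The call counts also rested on single libraries, whereas the median log2 fold change of all genes moved less. That median was 0.45 without line D7, 0.54 without line C2, 0.6 without wild-type replicate 1 and 0.43 without wild-type replicate 2. A fit without a library leaves 1 library in that group, so its counts can fall for lack of libraries alone. Without line D7, 9 genes were higher and 0 lower, without line C2 the numbers were 11 and 1, without wild-type replicate 2 they were 6 and 0, and without wild-type replicate 1 they were 3365 and 451. At an adjusted p below 0.1 the numbers were 5198 and 1018 with all libraries, 28 and 4 without line D7, 22 and 1 without line C2 and 3190 and 667 without wild-type replicate 2. Most of the genes called lower without wild-type replicate 1 were not among the 352 called lower with all libraries. At an unadjusted p below 0.05, 5750 genes were higher and 1240 lower with all libraries. The groups did not overlap for 68.1% of genes, where chance gives 33.3% for 2 libraries against 2 that differ by no common shift. A shift shared by many genes, such as the median of 0.49, also raises this share. It was not computed after rescaling, so the excess is not by itself a sign of change in single genes.

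Slchs (Solyc09g091510.2, chromosome 9) was the single gene that the table marks with a name. The mark is not spelled out, and chs is the usual symbol of chalcone synthase, the entry enzyme of flavonoid synthesis. Its level was 209 RPKM in line D7 and 53.4 RPKM in line C2, against 31.0 and 59.8 RPKM in the wild-type libraries. The transgenic mean was 131 ± 110 RPKM (SD, n = 2) and the wild-type mean 45.4 ± 20.3 RPKM (SD, n = 2). The log2 fold change was 1.28 with a standard error of 0.68 and did not pass the test (limma, adjusted p = 0.21). It lay 0.78 above the median of all genes. Line D7 was 4.6-fold above the wild-type mean, whereas line C2 was 1.18-fold above it and lay between the wild-type libraries. The lines differed by 3.9-fold, a difference without a replicate in either line. Without line D7 the log2 fold change of Slchs was 0.3, and without line C2 it was 2.25. Behind these values stood 4591 reads in line D7, 998 in line C2, 959 in wild-type replicate 1 and 1132 in wild-type replicate 2.

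The largest rises were in genes with 0 reads in both wild-type libraries. Solyc11g045150.1 (chromosome 11) stood at 1492 RPKM in line D7 and 858 RPKM in line C2, from 9431 reads. Against a floor of 3 reads over both wild-type libraries it was at least 3770-fold higher by the transgenic mean. Its log2 fold change of RPKM + 1 was 10.15 (standard error 0.36, limma adjusted p = 0.0022). Solyc11g063500.1 (chromosome 11) stood at 402 and 233 RPKM and was at least 624-fold higher against the same floor. Its log2 fold change was 8.26 (standard error 0.36, limma adjusted p = 0.0022). These p-values do not test the folds against the floor, and the wild-type zeros add no spread to the standard errors. With voom on the recovered reads the standard errors were 1.06 and 1.03, and the adjusted p was 0.022 for both genes. Altogether 20 genes had at least 10 RPKM in both transgenic libraries and 0 in both wild-type libraries, and 0 genes showed the opposite pattern. The same count was 0 for each of the 4 pairings of a transgenic with a wild-type library. Of the 23 genes that were at least 32-fold higher with at least 10 RPKM in both transgenic libraries, 3 had any wild-type read. The floor covers counting error only. Read handling that differed between the groups, or sequence that differs between the plants, could also give such zeros, as set out below.

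On the log2(RPKM + 1) scale, the 2 largest falls among called genes were in genes still read in transgenic fruit. A further 4 genes had at least 1 RPKM in both wild-type libraries and 0 in both transgenic libraries. Solyc10g083880.1 (chromosome 10) fell from 147 ± 25 RPKM in wild type to 15 ± 9.63 RPKM in transgenic fruit (SD, n = 2 each), a 9.8-fold lower mean (log2 fold change -3.35, standard error 0.47, limma adjusted p = 0.031). Solyc12g005750.1 (chromosome 12) fell from 11.2 ± 4.8 to 0.316 ± 0.116 RPKM (SD, n = 2 each; log2 fold change -3.15, standard error 0.41, limma adjusted p = 0.031). It rested on 3 transgenic and 118 wild-type reads, a ratio of 32.1 per read sequenced with an exact 95% counting interval of 10.7 to 157.8. With a pseudocount of 0.1 the order of the 2 falls was reversed (log2 fold changes -3.44 and -4.72), and with a pseudocount of 5 they were -3.01 and -1.57. For both falls the adjusted p was 0.068 with quantile normalization, 0.061 with no filter and 0.11 with the gene length correction, and it ranged from 0.02 to 0.19 over all settings. The log2 fold changes stayed about as large in these 3 settings, at -3.59 and -3.62 (standard errors 0.49 and 0.41), -3.35 and -3.15 (0.48 and 0.44), and -3.29 and -3.08 (0.45 and 0.38) in the same order. Their unadjusted p stayed below 0.001, but the number of genes with such a p fell from 518 to 179, 290 and 151, which makes the adjustment stricter. With the replicate number as a block the limma adjusted p was 0.063 for both. Each fall passed the threshold in 13 of 20 settings. Leaving out a library in turn gave log2 fold changes of -4 to -2.69 for Solyc10g083880.1 and -3.57 to -2.74 for Solyc12g005750.1.

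**Figure D1:**
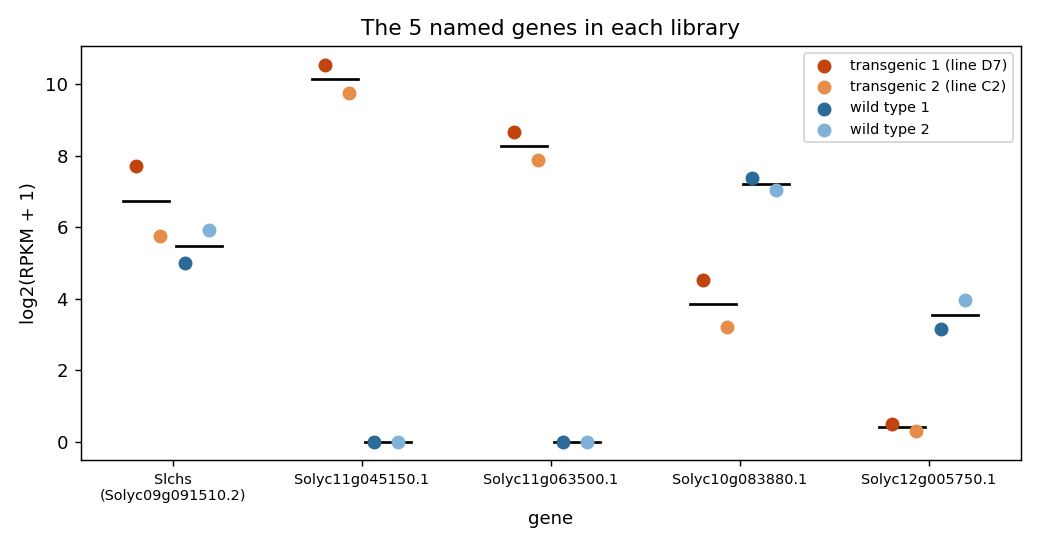
Level of the 5 named genes in each library, as log2(RPKM + 1) on the vertical axis; points are single libraries and black lines are means of the 2 libraries of a group. Slchs was at 209 RPKM in line D7 and at 53.4 RPKM in line C2, the 2 rising genes were at 0 in both wild-type libraries, and the 2 falling genes were lower in both transgenic libraries than in either wild-type library.

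As deposited, abundant fruit transcripts had lower values in the transgenic libraries, and the classes of genes with a mean below 50 RPKM had medians above 0. The 10 most abundant genes of a library took 18.7% and 18.9% of the summed RPKM in wild type, against 9.1% in line D7 and 9.6% in line C2. Among the 100 genes most abundant over all 4 libraries, 22 were called lower and 0 higher, with a median log2 fold change of -0.97. Choosing by one group favours a fall in the other, and the 100 most abundant genes of wild type had a median of -1.09 (26 lower, 0 higher). The 100 most abundant genes of transgenic fruit, where the choice favours a rise, had a median of -0.60 (15 lower, 4 higher). Of 245 genes with a mean of at least 500 RPKM, 43 were lower and 3 higher, with a median log2 fold change of -0.84 (95% bootstrap interval -0.91 to -0.75) as deposited and -1.48 with median-of-ratios scaling. Of 3037 genes between 10 and 20 RPKM, 878 were higher and 33 lower, with a median of 0.78 (0.74 to 0.83) as deposited and 0.18 with that scaling. The median of genes between 20 and 50 RPKM was 0.47 as deposited and turned to -0.14 with that scaling. Less abundant genes, from 1 to 2, 2 to 5 and 5 to 10 RPKM, had medians of 0.43, 0.68 and 0.88 as deposited. With that scaling these were 0.08, 0.22 and 0.32. Because RPKM is a share of each library, these levels are not independent of each other.

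**Figure D2:**
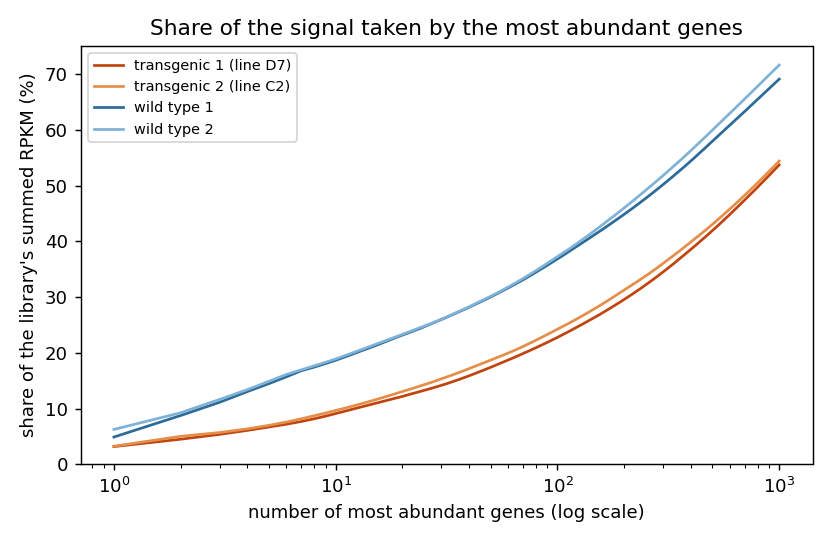
Share of a library's summed RPKM (vertical axis, percent) taken by its most abundant genes, added up from the most abundant gene to 1000 genes (horizontal axis, log scale), with a line per library. The 10 most abundant genes took 18.7% and 18.9% in the wild-type libraries and 9.1% and 9.6% in the transgenic libraries.

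Longer genes were higher in the transgenic libraries, except that the shortest class lay above the next 2. Among 361 genes of 4000 bases or longer, 287 were called higher and 0 lower, with a median log2 fold change of 1.76 (95% bootstrap interval 1.71 to 1.80) as deposited and 1.23 with median-of-ratios scaling. Among 1508 genes of 2500 to 3999 bases, 872 were higher and 0 lower, with a median of 1.44 (1.41 to 1.47). Genes of 300 to 499 bases had a median of -0.34 (-0.39 to -0.27) as deposited, with 87 called higher and 80 lower, and a median of -0.88 with that scaling. Of the 3485 genes of 300 to 799 bases, 230 were higher and 190 lower as deposited, against 67 and 479 with that scaling. The shortest genes, of 60 to 299 bases, had a median of -0.06 (-0.13 to 0.01) as deposited, with 118 higher and 62 lower. With that scaling their median was -0.53, with 30 higher and 110 lower. Genes of 500 to 799 bases had a median of -0.24 as deposited. Genes called higher had a median length of 2111 bases and genes called lower one of 574 bases, against 1241 bases for all genes tested. The log2 fold change increased by 0.39 per doubling of length, and by 0.34 to 0.43 in the 4 pairs of a transgenic with a wild-type library. The slope was 0.07 between the wild-type libraries and -0.02 between the transgenic lines. Across genes, which are not independent replicates, the log2 fold change and log2 length had a Pearson r of 0.44 and a Spearman rho of 0.54. With the length trend of each library removed, 18 genes were higher and 0 lower, and 16 of these 18 were at 0 in both wild-type libraries. At an adjusted p below 0.1 the numbers were 35 and 1, against 5198 and 1018 without the correction. At an unadjusted p below 0.05 they were 2068 and 1972, against 5750 and 1240, so that fewer genes were higher and more were lower.

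**Figure D3:**
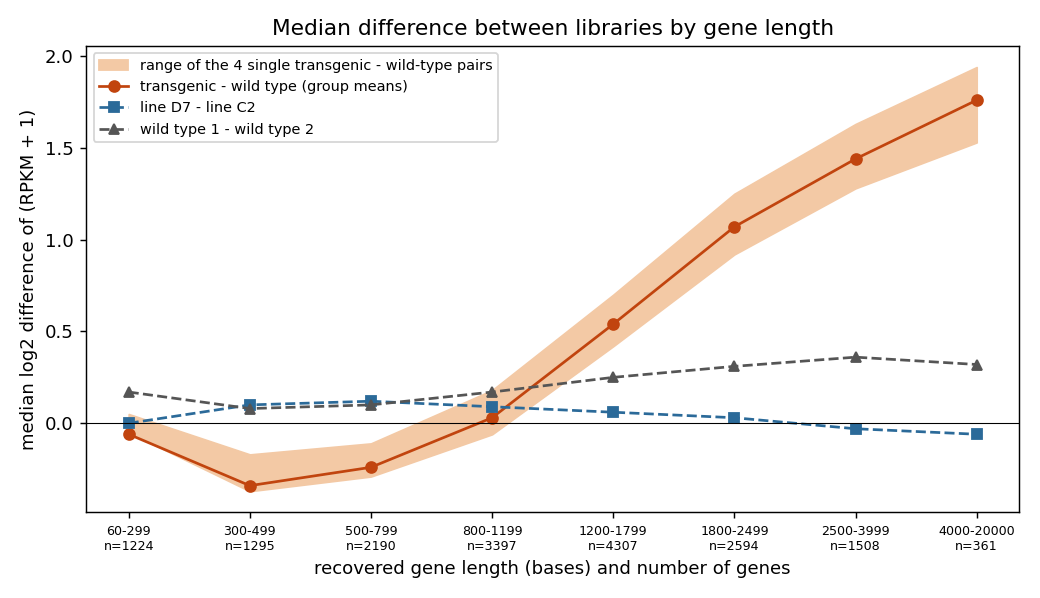
Median log2 difference of RPKM + 1 (vertical axis) in classes of recovered gene length (horizontal axis, bases, with the number of genes), for transgenic minus wild type, for line D7 minus line C2 and for wild-type replicate 1 minus replicate 2. The shaded band spans the 4 single pairs of a transgenic with a wild-type library. The group difference was -0.06 at 60 to 299 bases and went from -0.34 at 300 to 499 bases to 1.76 at 4000 bases or longer.

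The lines were closer to each other than to wild type. The median absolute log2 difference was 0.31 between line D7 and line C2 and 0.44 between the wild-type libraries, against 0.74 to 0.98 between a transgenic and a wild-type library. Of 12286 genes with a mean of at least 5 RPKM, 222 were at least 4-fold apart between the lines and 383 between the wild-type libraries, against 645 to 1634 between groups. Relative to the wild-type mean, 4214 genes were at least 2-fold higher in both lines, 544 were at least 2-fold lower in both, and 42 went opposite ways. Independent lists of these sizes would share 1731 and 90 genes, and unchanged lines with the same shared controls shared 221 and 223 on average in 100 simulations. The log2 fold changes of the lines correlated across genes with an r of 0.80, against 0.33 in these simulations. Their covariance was 0.83, against 0.14 simulated. With a separate wild-type library for each line, r was 0.50 or 0.60. The controls cannot be split with 2 libraries in each part, so part of the excess may come from the shared wild-type libraries. The simulated lines also held no shift of whole libraries and no trend with gene length. The real lines shared both, with a median log2 fold change of 0.54 in line D7 and 0.45 in line C2. How much of the excess comes from that shift and that trend, and not from single genes, was not tested.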

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

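The voom, length-correction, crossed-block, zero-gene and both top-10 settings were chosen after seeing the data. The counts of 3179 genes higher and 352 lower became 11 and 0 with no filter, 498 and 926 with median-of-ratios scaling, 17 and 0 with quantile normalization and 18 and 0 with the gene length correction. Scaling to the summed RPKM without the 10 most abundant genes gave 4657 genes higher and 212 lower, and leaving the reads of these genes out of the library totals gave 2284 and 425. Leaving out a library in turn gave 6 to 3365 genes higher and 0 to 451 lower. In these fits a group of 1 library was assumed to vary like the other group. The median log2 fold change of all genes, 0.49, turned to -0.05 with median-of-ratios scaling and to -0.03 with the gene length correction. The first centres genes read in every library and the second removes each library's trend. Both therefore bring this median close to 0 by construction, whatever its cause, and show no cause for the 0.49. For the changes in the counts the cause was not tested. At an adjusted p below 0.1 the main fit gave 5198 genes higher and 1018 lower. The loss was smaller there with no filter (4488 and 736) and with the replicate number as a block (3676 and 520), but not with the gene length correction (35 and 1). Quantile normalization gave 1960 higher and 1521 lower, so fewer genes were higher and more were lower than in the main fit. The numbers without single libraries are given above. Counts stayed within 1.5 times under both other pseudocounts, the stricter filter, eBayes without trend, robust eBayes, voom on the recovered reads (3529 and 332) and without genes at 0 in a whole group. Replicate numbers do not mark a shared plant, day or batch in the labels, and the deviations of same-numbered libraries correlated across genes at -0.16. With the replicate number as a block, 24 genes were higher and 0 lower, and 18 of these 24 were at 0 in both wild-type libraries. The crossed block pairs line D7 with wild-type replicate 2 and line C2 with wild-type replicate 1, and was added because of the negative correlation. With it, 4071 genes were higher and 816 lower. A pairing picked by its correlation in the same data lowers the residual spread, so the added calls are no support for it. The rises of Solyc11g045150.1 and Solyc11g063500.1 kept their direction and their call under every setting that tested them. Both genes were at 0 in both wild-type libraries, which no scaling, pseudocount, block or left-out library raises. Their direction was therefore largely fixed in advance, and these settings say nothing about the origin of the zeros. The fit without genes at 0 in a whole group left both genes out. Slchs kept its direction under every setting and passed the test only with the crossed block. The gene lists fixed in advance gave no values under any setting, and the models of raw reads were not run. Depth limits low genes: 3 reads in a gene of 1 kilobase correspond to 0.14 to 0.232 RPKM.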

Other observations

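The tests of a common gene length, of slopes within a genotype, of expected wild-type reads, of runs of neighbouring IDs, of library totals without the 10 most abundant genes and of the median in shorter genes were chosen after the patterns had been seen; the others were fixed before their results were computed. The excess of higher genes was spread over the chromosomes. On chromosomes 1 to 12 the median log2 fold change lay between 0.37 on chromosome 10 and 0.63 on chromosome 11, with 15.2% of genes called higher on chromosome 6 and 23.6% on chromosome 11. With median-of-ratios scaling these medians lay between -0.18 and 0.11. Genes on unplaced sequence had a median of -0.08 (95% bootstrap interval -0.18 to 0.06), with 21 of 173 called higher and 5 lower. Many of these genes were shorter than 1241 bases, the median of genes tested. Gene length was not taken into account in these medians, so they do not set unplaced sequence apart by location.

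A hypothesis was that neighbouring genes share their change beyond length and abundance. With the length trend and the median of abundance classes removed, and without the 20 genes at 0 in wild type, log2 fold changes of 10287 pairs of neighbouring IDs had a rank correlation of 0.18, against a 95th percentile of 0.016 in 9999 permuted gene orders (permutation p = 0.0001, the smallest they can give). The same correlation was 0.113 for the difference between the wild-type libraries and 0.125 for that between the lines, without the length correction. Neighbours may therefore vary together in any pair of libraries, and whether 0.18 exceeds those values was not tested.

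Longer genes were higher in the transgenic libraries, by 0.39 on the log2 scale per doubling of length. Different gene lengths for the groups are argued against, since 99.99% of genes gave whole reads at a length common to all 4 libraries. A link of abundance with length as the whole cause is argued against by a median slope of 0.38 within abundance classes, which ranged from 0.18 between 1 and 2 RPKM and 0.19 at 500 RPKM or more, both lower than the bound set for the median, to 0.50 between 20 and 50 RPKM. A difference in RNA integrity or fragment selection between the libraries could give such a slope and stays open: the largest slope between libraries of the same genotype was 0.07, between the bounds set for either answer, and the labels give no library batch, so preparation and genotype cannot be told apart. The slope stayed at 0.39 after the 10 most abundant genes were left out, but scaling shifts all genes of a library alike, so this says nothing about a few genes taking most of the reads. An effect of CsMYBF1 on genes that differ in length also stays open and was not tested.

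The 20 genes at 0 in both wild-type libraries with at least 10 RPKM in both transgenic libraries had a median length of 326 bases. Too few wild-type reads are argued against, since at the transgenic level at least 107 reads were expected for each of them in the wild-type libraries together. Of the 20 genes, 7 lay within 11 consecutive table positions on chromosome 1, a stretch with 6552 transgenic and 3 wild-type reads, and 5 stood directly beside another of the set, against a mean of 0.03 in 9999 random sets (permutation p = 0.0001, the smallest they can give). A candidate explanation is that reads shared between near-identical copies were handled differently for the 2 groups; runs of neighbours are consistent with that, but also with sequence that differs between the plants and with genes switched on together. Gene sequences and alignments were not analysed here, so these explanations cannot be told apart.

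More genes were higher than lower, with a median log2 fold change of 0.49. The 10 most abundant genes took 12.9% and 13.9% of the reads in wild type, against 4.9% and 5.0% in the transgenic libraries. All 10 had a log2 fold change below 0, so leaving their reads out of the library totals had to lower the median. That fall therefore does not show that they caused part of it. The median was still 0.38, so as the whole cause they are argued against. The test fixed earlier, which scaled to the summed RPKM without these genes and gave 0.69, does not decide, because that scaling with no gene left out already gave 0.83. A few genes beyond these 10 as the cause therefore stay open. As deposited the median was -0.09 (95% bootstrap interval -0.12 to -0.06) in genes shorter than the median length, against 0.97 in the others. These values met the rule set for the trend with gene length as its cause. With median-of-ratios scaling they were -0.64 against 0.44, and the slope on length was still 0.38 while the median of all genes was -0.05. A length trend can thus meet the rule whatever sets the median of all genes, so the rule cannot decide. For the calls, the trend as the whole cause stays open. Of the shorter genes 594 were called higher and 336 lower, which met the bound set against it, but that bound presumes the deposited scale: the numbers were 133 and 854 with median-of-ratios scaling and 424 and 407 with library totals without the 10 most abundant genes. Of the others 2585 were higher and 16 lower as deposited. A difference in RNA yield or in scaling between the groups stays open, since median-of-ratios scaling gave 498 higher and 926 lower, and so does an effect of the transgene.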
